A study of Zea mays with 6 samples.

How the data were processed

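RNA was measured in immature ears of 2 maize lines by sequencing of polyadenylated RNA. Per the labels, each library came from a pool of at least 50 separately grown plants, with 3 pools per line and a single stated batch. The lines are nearly isogenic recombinant inbred lines, that is, lines from a cross of teosinte (the wild ancestor of maize) with maize that share most of their genome and differ in a marked segment. A12 carries teosinte DNA at qKRN5.04b, a kernel row number locus on chromosome 5, and B46 carries maize DNA there. Groups and replicate numbers were taken from the sample titles.

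The authors deposited raw read counts per gene, whole numbers that sum to a different total in each library, without normalization. Beside them, the authors deposited FPKM values (fragments per kilobase of gene, scaled to library size) for the same genes and libraries. Within a library, each deposited FPKM value was the count divided by the gene length and by a constant of that library. That constant lay within 0.962 and 1.02 times the total count. The FPKM table therefore holds no information that the counts lack. HISAT2 2.0.5 and DESeq2 1.20.0 are named in the submitters' processing notes. The genome build, the read counter and whether strand was used are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies, cannot be told apart. Coordinates are printed as the count table lists them, without a build name.

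The table lists 42508 genes, of which 40651 have an identifier beginning with Zm00004b and 1857 are unnamed transcript models added by the submitters' pipeline. It gives no maize gene symbols. Names were read from its best Swiss-Prot match, present for 28164 genes, and its Pfam domains, present for 26574 genes. A name here is thus a similarity annotation, often to a rice or Arabidopsis protein, and several maize genes can carry the same name. The supplied reference gene table shared 0 identifiers with the files and was not used. All per-sample columns were used.

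Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low genes were removed with the default expression filter, which left 22741 genes. Libraries were scaled by TMM. Each gene was tested two-sided with the quasi-likelihood F-test, without covariates, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. All log2 fold changes are A12 minus B46, given with their standard error (SE), and "rose by" or "fell by" refers to that scale. CPM are library-scaled counts (counts per 1e6) after TMM scaling, given as mean ± SD over 3 libraries. Where every library of a line had 0 counts, the fold was computed against a floor of 3 counts per library and is written as a lower bound. Where a line had 1 to 3 counts in all, the ratio of counts is given with its 95% exact interval. Such bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

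Called genes were compared with all genes tested by Fisher's exact test: two-sided per chromosome, and one-sided in fixed windows of 5 Mb with at least 10 tested genes. Passing windows separated by no more than 1 window were joined into blocks. A two-sided Fisher's exact test compared direction inside and outside these regions. Gene lists for this tissue were written before the data were examined, by symbol or by description, with markers of other tissues among them. Lists with at least 5 tested members were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, then with an estimated correlation, and with fry. Of 23 lists, 20 could be tested. The list of meristem size regulators matched 3 tested genes, and the symbol lists for auxin synthesis and for floral MADS-box genes matched 0 tested genes, since the table lacks those symbols. Transcription factor families from the submitters' family column were compared by Fisher's exact test. That column names a family for 23173 genes, among them proteins that are no transcription factors, and its families are read with that reserve. The FPKM values were tested with limma on log2(FPKM + 0.1) for genes with a mean of at least 0.5.

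Genes were named by a rule written before the data were examined. It took the 10 largest rises and the 10 largest falls among called genes with a mean count of at least 50 in the higher line and no overlap between lines. It also took up to 4 called members per list with the lowest adjusted p, all glutaredoxins that were called or lie on chromosome 5, the 8 called genes of lowest adjusted p in the dense chromosome 5 windows, and 20 ear architecture regulators by symbol, of which 5 were matched. For the largest falls, 8 called genes without a description were passed over. Unnamed transcript models that the rule selected are described without their identifiers.

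The procedure was tested on counts simulated from the means and library sizes of A12 and B46, with 200 genes changed. Of 22503 genes run, edgeR recovered 5.97% of those changed 1.5-fold, 47.8% of those changed 2-fold and 83.3% of those changed 4-fold, with 5 false calls. In the same simulation, DESeq2 recovered 20.9%, 70.1% and 86.4% over 22741 genes, with 52 false calls. For limma on simulated FPKM of 22345 genes, the shares were 2.99%, 41.8% and 77.3%, with 7 false calls. The simulated window and list were both found with 0 others, and counts without any change gave 0 calls among 22520 genes. Genes were simulated independently of each other, so the list step was not tested under correlation between genes. In the real data that correlation was estimated at 0.42 for the histone list and 0.22 for the ribosomal protein list.

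Alternatives fixed in advance were DESeq2 size factors and library totals in place of TMM, no filter and a stricter filter, DESeq2 1.42.0 with its defaults and without its filters, the replicate number as a block, a test against a fold of 1.5, an adjusted p under 0.01, omission of each library in turn, other window sizes and offsets, lists without chromosome 5 genes, and other pseudocounts and filters for FPKM.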

Results

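The data describe the early ear of 2 nearly isogenic maize lines that differ in a chromosome 5 segment holding the kernel row number locus qKRN5.04b. Line A12 carries the teosinte version and line B46 the maize version. Ears were taken from plants with 6 to 9 leaves, as primordia of 1.5 to 2.0 mm at the stage where the inflorescence meristem gives rise to spikelet pair meristems. Each line has 3 libraries, and each library is a pool of at least 50 plants. Total gene counts were 15156035, 15432882 and 15145371 in B46 replicates 1, 2 and 3. They were 14625831, 14958051 and 15675012 in A12 replicates 1, 2 and 3. Between 26626 and 27791 genes had a count in a library, and the 10 highest genes took 2.57% to 3.44% of the counts.

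Similarity within and between lines overlapped. Across genes, which are not independent replicates, the correlation of log2 CPM was 0.937 to 0.989 within a line and 0.906 to 0.940 between lines. The lowest value within a line belonged to A12 replicates 1 and 2, and 4 of the 9 pairs between lines lay above it, all of them with A12 replicate 2 or 3. In the 500 most variable genes, the first principal component held 77.4% of the variance and separated the lines. The component after it held 15.7% and separated A12 replicate 1, at -25.3, from A12 replicate 2, at 31.4. Within a line, no pair of libraries had counts alike within sampling noise, since chi-square per degree of freedom was 3.08 to 43.9 for the 6 pairs.

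The first comparison asks which transcripts differ between ears with the teosinte and the maize segment. Of the 10 largest rises in A12, 8 were genes annotated as MADS-box factors, which went from a mean under 0.5 CPM in B46 to means of 15.7 to 84.6 CPM in A12. The gene annotated as rice FZP, which sets spikelet and floret identity, rose from 0.280 ± 0.133 to 19.8 ± 0.503 CPM (SD, n = 3). In the opposite direction, the gene annotated as LIGULELESS 1 fell from 5.40 ± 0.373 to 0.182 ± 0.258 CPM, and many genes of chromosome 5 between 145 and 185 Mb had few or no reads in A12.

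Of 22741 genes tested with edgeR, 2242 were called, or 9.86%, with 1048 higher and 1194 lower in A12. A log2 fold change of at least 1 in size was seen for 1104 of them, 505 higher and 599 lower, and the median size over all called genes was 0.98. In all 2242 the values of the lines did not overlap. Over all genes tested, 33.4% had no overlap, where chance gives 10% for 3 against 3. At an unadjusted p under 0.05 there were 6175 genes. The count rested strongly on single libraries: it was 714 without B46 replicate 1, 432 without B46 replicate 2, 1410 without B46 replicate 3, 4446 without A12 replicate 1 and 401 without A12 replicate 3.

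Among the ear architecture regulators and the list of spikelet pair fate and determinacy genes, changes went both ways. Of the list's 11 tested members, 2 rose, 3 fell and 6 were not called (6 called when adjusted over the list alone). Its median log2 fold change was -1.003, and camera gave an adjusted p of 0.254 (adjusted p = 0.581 with an estimated correlation). The 2 that rose are both annotated as teosinte glume architecture 1, the SBP-box gene that controls the casing around the teosinte kernel. Zm00004b021095, on chromosome 4 from 45784966 to 45789775, rose from 3.91 ± 0.6 to 35.3 ± 5.50 CPM (SD, n = 3; log2 fold change 3.17, SE 0.18, edgeR adjusted p = 0.00027). Its neighbour Zm00004b021099, from 46089235 to 46093692, had a log2 fold change of 2.19 (SE 0.40, edgeR adjusted p = 0.019), and reads of such similar copies can be split between them. The 3 that fell are annotated as LIGULELESS 1, a regulator of ligule and branch base formation, LG2 of the same pathway, and RAMOSA 3, a trehalose phosphate phosphatase that limits ear branching. LIGULELESS 1 (Zm00004b006064, chromosome 2, 4218454 to 4222179) had 86, 88 and 77 reads in B46 against 7, 1 and 0 in A12 (log2 fold change -4.84, SE 0.71, edgeR adjusted p = 0.0091). LG2 (Zm00004b018395, chromosome 3) was at 22.4 ± 2.61 CPM in B46 and 10.3 ± 0.968 in A12 (log2 fold change -1.12, SE 0.14, edgeR adjusted p = 0.0054). RAMOSA 3 (Zm00004b037360, chromosome 7) varied within both lines, with 2768, 2490 and 908 reads in B46 and 136, 535 and 424 in A12 (log2 fold change -2.43, SE 0.56, edgeR adjusted p = 0.039). Without B46 replicate 2, the edgeR adjusted p was 0.0576 for LIGULELESS 1, 0.143 for RAMOSA 3 and 0.0920 for Zm00004b021099. The last also missed the threshold without B46 replicate 1, B46 replicate 3 or A12 replicate 3, and RAMOSA 3 without B46 replicate 1 or A12 replicate 3.

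FZP (Zm00004b037561, chromosome 7, 176792976 to 176793914) had 5, 6 and 2 reads in B46 and 298, 278 and 302 in A12 (log2 fold change 6.10, SE 0.28, edgeR adjusted p = 0.00019). It was called in all 15 alternative analyses. The remaining regulators that were matched were not called by edgeR. KNOTTED 1 (Zm00004b005000), which maintains the meristem, was at 507 ± 57.0 CPM in B46 and 429 ± 132 in A12 (adjusted p = 0.54). THICK TASSEL DWARF 1 (Zm00004b012516) and FASCIATED EAR 2 (Zm00004b021988), receptors that restrict meristem size, had log2 fold changes of -0.40 (SE 0.28, edgeR adjusted p = 0.40) and -0.19 (SE 0.09, edgeR adjusted p = 0.21). TEOSINTE BRANCHED 1 (Zm00004b004880), which represses branch outgrowth, had a log2 fold change of -0.53 (SE 0.21, edgeR adjusted p = 0.16). In the list of meristem size genes 0 of 3 were called, and in the KNOX and BELL list 0 of 5 (0 when adjusted over the list alone; camera adjusted p = 0.710, or adjusted p = 0.880 with an estimated correlation). For both lists, edgeR gave 0 genes at an unadjusted p under 0.05, and DESeq2 and limma on FPKM called 0.

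**Figure D1:**
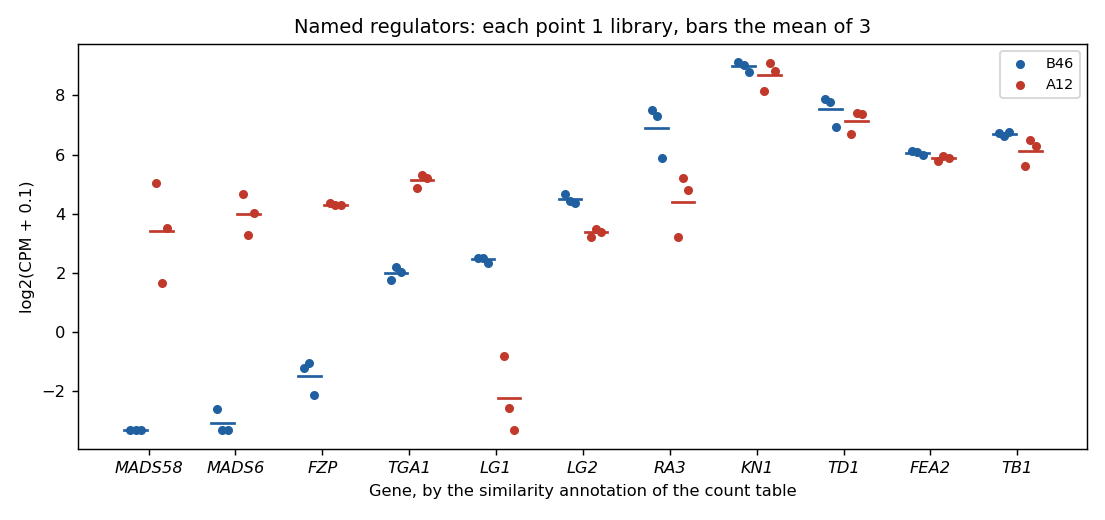
Expression of 11 named regulators, by annotation name on the horizontal axis and log2(CPM + 0.1) on the vertical axis, with 1 point per library (3 of B46 in blue, 3 of A12 in red) and a bar at the mean of each line. MADS58, MADS6, FZP and TGA1 lie higher in A12 and LG1, LG2 and RA3 lower, while KN1, TD1, FEA2 and TB1 overlap or lie close (edgeR adjusted p = 0.54, 0.40, 0.21 and 0.16).

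The 8 MADS-box genes among the largest rises belong by annotation to classes that specify flowers. MADS58 (Zm00004b030241, chromosome 6), a class C floral organ identity factor in rice, had 0 reads in all B46 libraries and 478, 44 and 175 in A12, at least 80.8-fold higher (edgeR adjusted p = 0.027). Of 2 genes annotated as MADS6, a floral meristem factor, Zm00004b022334 had 1 read in all of B46 and 373, 140 and 252 in A12, a ratio of 799 (95% interval 143 to 31609; edgeR adjusted p = 0.0010). The other, Zm00004b014719 on chromosome 5 from 199319703 to 199327631, rose by 7.80 on the log2 scale (SE 0.65, edgeR adjusted p = 0.0013). The 2 genes annotated as MADS1, Zm00004b034170 and Zm00004b000789, rose by 7.80 (SE 0.98) and 7.74 (SE 1.06; edgeR adjusted p = 0.0055 and 0.0072). Genes annotated as MADS7 (Zm00004b003251) and MADS8 (Zm00004b009291, Zm00004b036450), class E factors, rose by 8.45 (SE 1.23), 8.45 (SE 1.39) and 7.76 (SE 1.42; edgeR adjusted p = 0.0088, 0.013 and 0.018). The other 2 of the 10 encode a BX6-like enzyme of benzoxazinoid synthesis, at least 17.9-fold higher (Zm00004b010580, 0 reads in B46 against 49, 54 and 51), and a flavonoid methyltransferase-like protein, at least 27.8-fold higher (Zm00004b008215). A12 libraries differed strongly in these genes: MADS7 was at 70.5 ± 68.2 CPM and MADS1 (Zm00004b000789) at 84.6 ± 67.9. MADS58 reads were highest in A12 replicate 1 and lowest in A12 replicate 2, and so was the median of the photosynthesis genes relative to the B46 mean (1.18, -0.63 and 0.26 in replicates 1, 2 and 3). The MADS58 call was lost without any 1 of B46 replicates 1, 2 and 3 or A12 replicate 3 (highest edgeR adjusted p 0.0912), as were those of both MADS8 genes (0.0924 and 0.104) and Zm00004b008215 (0.0936). MADS7 was lost without B46 replicate 2 (0.0663).

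The 10 largest falls all lay on chromosome 5 between positions 149055837 and 180771855. Zm00004b013550, a TMK2-like receptor kinase from 149105542 to 149113810, had 867, 810 and 819 reads in B46 and 0 in A12, at least 265-fold lower (edgeR adjusted p = 0.00019). Zm00004b014179, annotated as metal tolerance protein 5 (180454289 to 180459357), was at least 164-fold lower. SOSEKI 3, a cell polarity protein (Zm00004b014186), a coatomer subunit of vesicle coats (Zm00004b013548) and a beta-carotene hydroxylase (Zm00004b014082) were at least 105-fold, 83.1-fold and 37.5-fold lower. A pentatricopeptide repeat protein (Zm00004b014187) had 261, 324 and 381 reads in B46 and 1 in all of A12, a ratio of 925 (95% interval 166 to 36557). The other 4 were unnamed transcript models, at least 271-fold, 113-fold, 105-fold and 36.5-fold lower. All 10 were called in each of the 15 alternative analyses.

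The next comparison asks where in the genome the called genes lie, given that the lines are stated to differ on chromosome 5. Chromosome 5 held 337 called genes among 2596 tested, 12.98% against 9.47% elsewhere (odds ratio 1.43, 95% interval 1.26 to 1.61; Fisher's exact test, adjusted p = 5.6e-07 over 10 chromosomes). No other chromosome was enriched, the closest to the threshold being chromosome 3 with fewer calls (odds ratio 0.849, adjusted p = 0.138). Of 413 windows of 5 Mb, 8 passed, all on chromosome 5. With windows of 1 Mb, 6 passed, and 1 of them lay on chromosome 7 (165 to 166 Mb, 8 of 14 genes called, 7 of them higher in A12; Fisher's exact test, adjusted p = 0.0053). The 5 Mb window around it did not pass (adjusted p = 0.281). The 5 Mb windows that passed formed a short block at 0 to 5 Mb, with 42 of 194 genes called, and a long block at 145 to 185 Mb, with 144 of 402 called. The long block was made of the window at 145 to 150 Mb (15 of 32), those from 155 to 185 Mb (122 of 347) and the window between them, which did not pass.

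Genes in the long block were mostly lower in A12. Of its 144 calls, 122 were lower and 22 higher, 84.7% lower against 51.1% for calls elsewhere (odds ratio 5.30, 95% interval 3.32 to 8.85; Fisher's exact test p = 3.8e-16). In this block, 36 tested genes had 3 reads or fewer in all of A12, and 31 had 0, while 0 genes were that low in B46. On the other chromosomes only 14 of 20145 genes were that low in A12 (odds ratio 141, 95% interval 73.6 to 288, Fisher's exact test p = 4.7e-51). This test is not independent of how the block was found. The block was chosen for its density of called genes, and all 36 are among its lower calls. Besides the genes above, those of low adjusted p include a gene annotated as ribosomal protein S4 (Zm00004b013619, 154099409 to 154104492, 69.4 ± 4.22 against 0.133 ± 0.115 CPM). It lies in the window of the block that did not pass. A serine/threonine kinase (Zm00004b014246, 182671950 to 182679168) had 256, 278 and 372 reads in B46 against 1 in all of A12. Zm00004b013863 and Zm00004b013939 fell as well (edgeR adjusted p = 0.00019 and 0.00027). The ABA receptor PYL9-like gene Zm00004b013641, at 155.2 Mb, fell by 2.34 (SE 0.26, edgeR adjusted p = 0.0037).

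The short block went the other way. Of 42 calls, 31 were higher and 11 lower in A12, 26.2% lower against 53.8% for calls elsewhere (odds ratio 0.305, 95% interval 0.138 to 0.628; Fisher's exact test p = 0.00046). A linker histone H1 gene (Zm00004b011064, 4192124 to 4193550) rose from 76.6 ± 36.1 to 716 ± 117 CPM (log2 fold change 3.22, SE 0.39, edgeR adjusted p = 0.0049), and its neighbour Zm00004b011065 rose by 1.13 (SE 0.14, edgeR adjusted p = 0.0054). The ribosomal protein S2 gene Zm00004b011032 rose by 0.78 (SE 0.08, edgeR adjusted p = 0.0035). In the opposite direction from most of the block, Zm00004b010988, annotated as a histidine kinase (2928831 to 2931808), fell by 5.78 (SE 0.54, edgeR adjusted p = 0.0021). Both blocks together had 127 lower and 52 higher calls in the passing windows, 70.9% against 51.7% elsewhere (odds ratio 2.28, 95% interval 1.62 to 3.25; Fisher's exact test p = 6.8e-07).

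**Figure D2:**
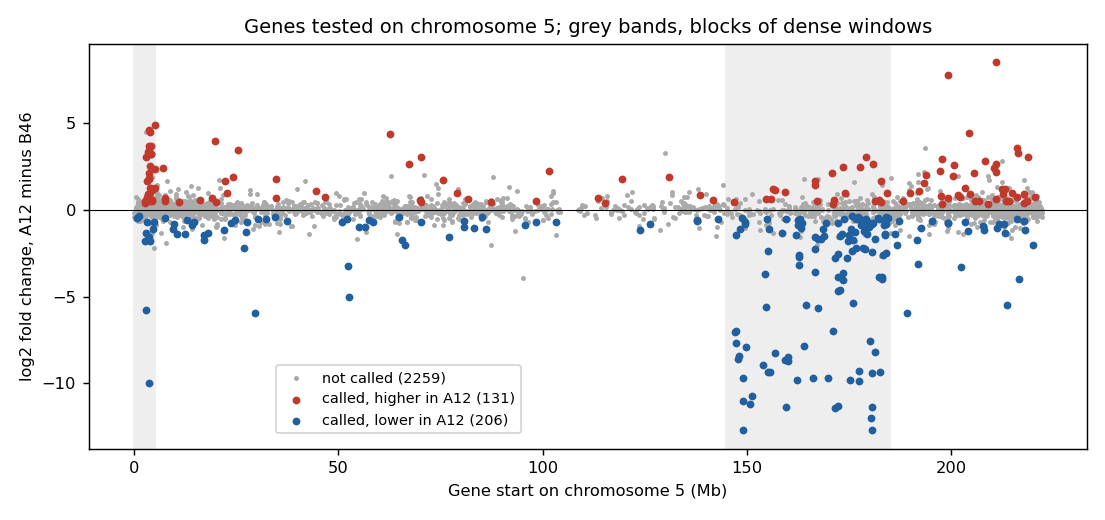
Genes tested on chromosome 5, by gene start in Mb on the horizontal axis and log2 fold change (A12 minus B46) on the vertical axis, with called genes higher in A12 in red (131), lower in blue (206) and others in grey. Grey bands mark the blocks of dense windows: in the band at 145 to 185 Mb 122 of 144 called genes lie below 0, and in the band at 0 to 5 Mb 31 of 42 lie above 0.

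The series title names a glutaredoxin, ZmGrx5, a class of small redox enzymes that act on protein thiols. Which identifier is that gene is not given in the sources used here. Of 43 tested genes annotated as glutaredoxins or by that domain, 2 rose, 2 fell and 39 were not called (4 called when adjusted over the list alone). GRXS1 (Zm00004b026663, chromosome 8) fell from 11.4 ± 1.15 to 4.70 ± 0.964 CPM (log2 fold change -1.27, SE 0.20, edgeR adjusted p = 0.012), and GRXC3 (Zm00004b007664, chromosome 2) fell by 0.61 (SE 0.14, edgeR adjusted p = 0.042). On chromosome 1, Zm00004b004064 rose by 2.22 (SE 0.40, edgeR adjusted p = 0.018) and Zm00004b004487 by 1.11 (SE 0.21, edgeR adjusted p = 0.022). On chromosome 5, 7 glutaredoxins were tested and 0 were called by edgeR, with 1 at an unadjusted p under 0.05, and 0 by DESeq2 or limma on FPKM. In the long block, GRXC3-like Zm00004b013885 (168684271 to 168684663) had 246, 235 and 238 reads in B46 and 69, 186 and 185 in A12 (log2 fold change -0.65, SE 0.34, edgeR adjusted p = 0.26). GRXS11-like Zm00004b013795 (163817041 to 163834132) had 70, 68 and 71 reads against 83, 80 and 91 (log2 fold change 0.34, SE 0.18, edgeR adjusted p = 0.26). The other 5 had log2 fold changes between -0.22 and 0.69. Taken as a list, glutaredoxins had a median of 0.18 and a camera adjusted p of 0.0923 (adjusted p = 0.581 with an estimated correlation, and 0.0488 without A12 replicate 2). All 4 calls were lost without B46 replicate 2 or A12 replicate 3 (edgeR adjusted p = 0.0696, 0.168, 0.0934 and 0.106 without the latter, in the order given). All but that of GRXS1 were also lost without B46 replicate 1 or 3, and that of GRXC3 without A12 replicate 2.

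Hormone genes changed in small subsets. Of 63 auxin response factors and Aux/IAA genes, the transcription factors and repressors of auxin signalling, 11 rose and 2 fell (25 called when adjusted over the list alone; median 0.09, camera adjusted p = 0.0923, or adjusted p = 0.482 with an estimated correlation). The list passed camera without B46 replicate 1 or A12 replicate 2, and it passed fry (adjusted p = 0.0238). ARF12 (Zm00004b040537) rose from 58.9 ± 1.73 to 128 ± 10.9 CPM, ARF25 (Zm00004b002861) from 99.0 ± 9.63 to 228 ± 14.7, and IAA31 (Zm00004b017259) from 3.56 ± 0.513 to 13.5 ± 0.904 (edgeR adjusted p = 0.0014, 0.0017 and 0.0019). Of 51 genes with cytokinin or response regulator terms in their description, which need not all act in cytokinin signalling, 5 rose and 10 fell (22 when adjusted over the list alone). The median was -0.18, with a camera adjusted p of 0.137 (adjusted p = 0.550 with an estimated correlation). The list passed without B46 replicate 3 (camera adjusted p = 0.0423) and with fry (adjusted p = 0.0466). A cytokinin hydroxylase (Zm00004b035931) had a log2 fold change of -3.02 (SE 0.44, edgeR adjusted p = 0.0091), and its adjusted p was 0.0602 without B46 replicate 2 and 0.0596 without A12 replicate 3. Of 33 gibberellin genes, 2 rose and 5 fell (10 when adjusted over the list alone). The median was -0.15, with a camera adjusted p of 0.140 (adjusted p = 0.499 with an estimated correlation, 0.0079 with fry). The 2 genes annotated as gibberellin 2-beta-dioxygenase 3, which inactivates gibberellin, went opposite ways: Zm00004b025134 had a log2 fold change of 2.51 (SE 0.20) and Zm00004b018931 of -1.80 (SE 0.17; edgeR adjusted p = 0.0013 and 0.0020). A short gene annotated as the DELLA repressor DWARF8 (Zm00004b013529, chromosome 5, 147366137 to 147366601) had 26, 21 and 31 reads in B46 and 0 in A12, at least 8.30-fold lower (edgeR adjusted p = 0.0076). Of 66 jasmonate genes, 7 fell and the other 59 were not called (7 when adjusted over the list alone; median -0.10, camera adjusted p = 0.254, or adjusted p = 0.719 with an estimated correlation). Those that fell include the synthesis enzyme allene oxide synthase 2 (Zm00004b000842), with a log2 fold change of -2.72 (SE 0.47, edgeR adjusted p = 0.015), though the call was lost without B46 replicate 2 or A12 replicate 3 (adjusted p up to 0.0854).

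Of 29 genes with an SBP-box term in their description, regulators of phase change and inflorescence branching, 4 rose and 6 fell (16 when adjusted over the list alone). The median was -0.16, with a camera adjusted p of 0.254 (adjusted p = 0.581 with an estimated correlation). Of 31 genes with the SBP domain, a group chosen after the results were seen, 7 rose and 6 fell. Their median was -0.06, with a camera adjusted p of 0.804 (adjusted p = 0.859 with an estimated correlation). SPL14 (Zm00004b023553) fell from 80.4 ± 12.3 to 36.8 ± 1.50 CPM (edgeR adjusted p = 0.0043), and SPL16 (Zm00004b036448) rose from 37.4 ± 2.05 to 65.8 ± 5.59 CPM (edgeR adjusted p = 0.0052). Of 49 flowering time genes, 4 rose and 3 fell (9 when adjusted over the list alone; camera adjusted p = 0.792, or adjusted p = 0.880 with an estimated correlation), with a median of 0.01 while camera pointed down. The CEN-like 2 gene Zm00004b021735, of the class that delays flowering, fell by 6.43 (SE 0.95, edgeR adjusted p = 0.0093, but 0.0640 without A12 replicate 3).

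Histone and ribosomal protein lists had small positive medians in A12 and passed camera only with the preset correlation. Of 86 genes with histone names or domains, linker histones included, 17 rose and 1 fell (37 when adjusted over the list alone), with a median of 0.47 and a camera adjusted p of 1.5e-07 (adjusted p = 0.581 with an estimated correlation, 0.120 with fry). Of 448 genes with a ribosomal protein term in their description, which need not all encode ribosomal proteins, 32 rose and 10 fell (71 when adjusted over the list alone). Their median was 0.24, with a camera adjusted p of 3.4e-08 (adjusted p = 0.581 with an estimated correlation, 0.0975 with fry). The shift of the histone genes was uneven across libraries, the median difference from the B46 mean being 0.10, 0.67 and 0.62 in A12 replicates 1, 2 and 3. Of 79 genes named as cyclins or cyclin-dependent kinases, which need not all drive the cell cycle, 1 rose and 9 fell (10 when adjusted over the list alone). The median was 0.02 while camera pointed down (camera adjusted p = 0.347, or adjusted p = 0.688 with an estimated correlation). With fry, which also pointed down, the list passed (adjusted p = 0.0305). Cyclin-D5-2 (Zm00004b004588) fell from 9.73 ± 0.317 to 0.111 ± 0.0726 CPM, and the CDKC-2-like genes Zm00004b035653 and Zm00004b027928 had log2 fold changes of -4.09 (SE 0.18) and -6.42 (SE 0.40; edgeR adjusted p = 0.00026, 0.00019 and 0.00041). Of 144 glutathione S-transferases and thioredoxins, 13 rose and 8 fell (32 when adjusted over the list alone; median 0.08, camera adjusted p = 0.347, or adjusted p = 0.606 with an estimated correlation).

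The defence list pointed down. Of 126 members, 4 rose and 11 fell (19 when adjusted over the list alone), with a median of -0.23 and a camera adjusted p of 0.0089, which was lost with an estimated correlation (adjusted p = 0.482), without the low count filter (0.199) and without B46 replicate 3 (0.111), and was 0.0305 with fry. An RPP13-like resistance gene (Zm00004b030162) fell from 23.4 ± 1.07 to 5.65 ± 0.954 CPM and a benzoxazinoid glucoside glucosidase gene (Zm00004b038344) from 5.95 ± 1.96 to 0.314 ± 0.155 (edgeR adjusted p = 0.00093 and 0.0035). Chitinase 1 (Zm00004b017263) went the other way, with 1 read in all of B46 and 25, 54 and 27 in A12, a ratio of 111 (95% interval 19.5 to 4415). Of 249 genes with heat shock or folding terms in their description, 5 rose and 17 fell (21 when adjusted over the list alone). The match is by text, and the falls include Zm00004b010988, annotated as a histidine kinase. The list had a median of -0.08 and a camera adjusted p of 0.137 (adjusted p = 0.462 with an estimated correlation, 0.0079 with fry). The 24.1 kDa mitochondrial heat shock protein (Zm00004b031568) had a log2 fold change of -3.29 (SE 0.17) and heat shock protein 81-1 (Zm00004b036324) of -1.43 (SE 0.10; edgeR adjusted p = 0.00019 and 0.00053). Of 84 water deficit genes, 4 rose and 4 fell (7 when adjusted over the list alone; median 0.10, camera adjusted p = 0.408, or adjusted p = 0.802 with an estimated correlation). Of 161 WRKY and ethylene-responsive factors, a list that includes FZP, 13 rose and 8 fell (26 when adjusted over the list alone; median 0.05, camera adjusted p = 0.971, or adjusted p = 0.984 with an estimated correlation).

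Marker lists of other tissues did not pass camera. Of 79 genes with photosynthesis terms in their description, taken as markers of green leaf or husk, 1 rose and 3 fell (4 when adjusted over the list alone). The terms include phosphoenolpyruvate carboxylase and malic enzyme, so not every member need be a marker of green tissue. The list had a median of 0.43 and a camera adjusted p of 0.361 (adjusted p = 0.880 with an estimated correlation). Their median difference from the B46 mean was 1.18 in A12 replicate 1, -0.63 in A12 replicate 2 and 0.26 in A12 replicate 3. Without A12 replicate 2 the list passed, with a camera adjusted p of 1.3e-05. Of 58 secondary wall and lignin genes, vascular markers, 5 rose and 2 fell (7 when adjusted over the list alone; median 0.10, camera adjusted p = 0.254, or adjusted p = 0.711 with an estimated correlation). Of 43 pollen and anther genes, 4 rose and 2 fell (13 when adjusted over the list alone; median 0.27, camera adjusted p = 0.0923, or adjusted p = 0.581 with an estimated correlation), and this list passed without A12 replicate 2 (camera adjusted p = 0.010) or B46 replicate 3 (0.0319).

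**Figure D3:**
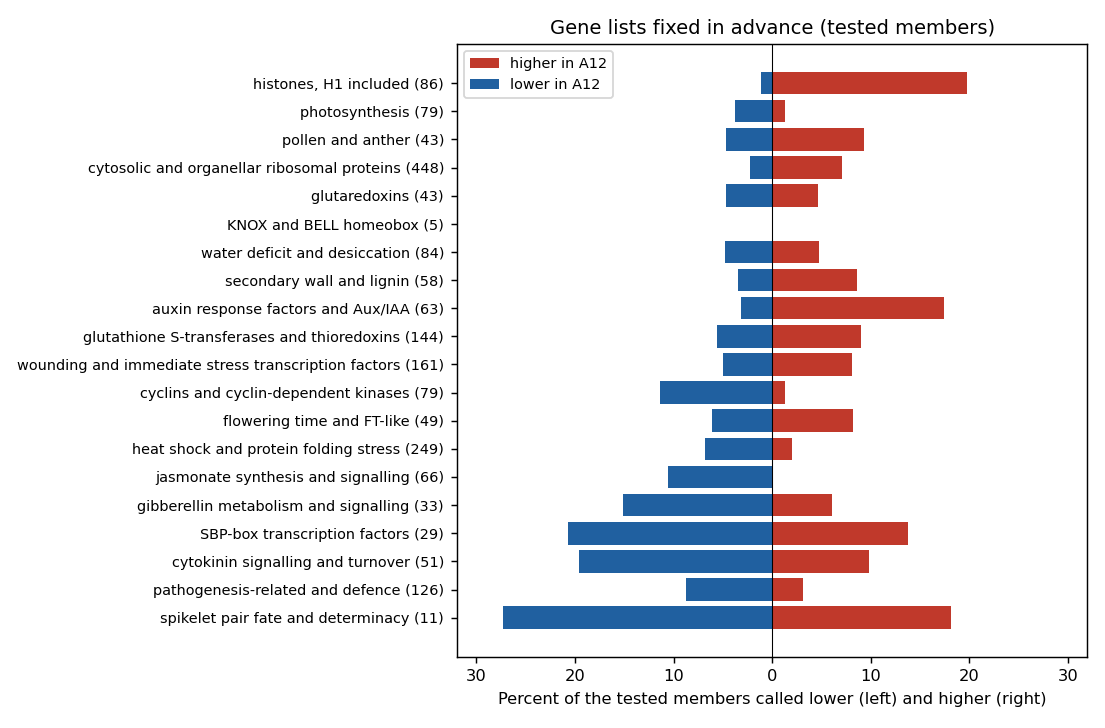
Share of the tested members of each of 20 gene lists (number tested in brackets) that were called lower in A12 (blue, left) or higher in A12 (red, right), in percent on the horizontal axis. Histones, linker histone H1 included, show 17 higher and 1 lower of 86, and defence genes 4 higher and 11 lower of 126.

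Of 55 transcription factor families in the submitters' family column, 3 held more called genes than the rest. These were HD-ZIP with 38 of 222 (17.1%, odds ratio 1.90), MYB with 63 of 425 (14.8%, odds ratio 1.61) and MIKC-type MADS with 35 of 203 (17.2%, odds ratio 1.92). Each had a Benjamini-Hochberg adjusted p of 0.022 in Fisher's exact test. The column is much wider than its names. Only 44 tested genes carried a MADS DNA-binding or K-box domain, and 51 matched homeodomain-leucine zipper genes. Most members of the MADS family in this column are thus no MADS factors by domain. The number of families passing was 1 without A12 replicate 3 and 6 without A12 replicate 2.

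The FPKM values gave a similar set. Of 23264 genes tested with limma, 1975 were called, 930 higher and 1045 lower in A12, and 6098 had an unadjusted p under 0.05. Of these 1975, 1842 were also called from the counts, all in the same direction. Since the FPKM values are rescaled counts, this checks the test used and is no second measurement. With limma, 569 genes were called without B46 replicate 1, 332 without B46 replicate 2, 1095 without B46 replicate 3, 3882 without A12 replicate 1 and 367 without A12 replicate 3.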

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

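Alternatives for windows, families and sample correlations under other fits, the blocks taken singly and the added gene groups were chosen after the data were seen. The number of called genes, 2242, became 3492 with DESeq2, 513 against a fold of 1.5, 510 at an adjusted p under 0.01, and 401 to 4446 with 1 library left out. Fewer libraries and stricter thresholds enter some of these by construction, and the cause of the rest was not tested. It was 2266 with RLE scaling, 2399 (892 higher) with library totals, 2182 without a filter, 2290 with a stricter filter and 3249 with DESeq2 without its filters. No called gene changed sign under any alternative. That says little about stability, since in all 2242 the values of the lines did not overlap. Of 164 named called genes, 76 stayed called under all of their alternatives and 88 were lost under at least 1, with 77 lost without A12 replicate 3 and 73 without B46 replicate 2. With the replicate number as a block, edgeR called 967 genes, 952 of them also called without it, and limma on FPKM 718. The numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.120, -0.0136 and 0.00541, and A12 replicate 2 correlated best with B46 replicate 1, at 0.152. The FPKM count ranged from 332 to 3882 with 1 library left out.

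The chromosome 5 odds ratio stayed above 1 and past its threshold in all alternatives (1.24 to 3.05), and 6 to 8 windows passed, all on chromosome 5 apart from 1 window of 1 Mb on chromosome 7. With 1 library left out, the odds ratio was 1.24 to 3.05, 7 to 8 windows passed, and 67.2% to 82.3% of calls in the windows were lower. The 0 to 5 Mb block alone reversed that direction, with 26.2% lower. Of 3 passing lists, 0 remained past the threshold with an estimated correlation, where 1 list had an unadjusted p under 0.05. Fry, which asks only whether a list's genes move one way, passed 6. Of these only the defence list is among those 3 (histones 0.120, ribosomal proteins 0.0975). The others that passed fry were the gibberellin, heat shock, auxin response, cyclin and cytokinin lists. Without each library, 3 to 7 lists passed, 7 without A12 replicate 2. Of 3 families, 0 passed with library totals, 1 with a stricter filter, 1 with the replicate block, 1 at an adjusted p under 0.01 and 1 to 6 with a library left out. The lowest correlation within a line rose from 0.937 to 0.967 without a filter. The cause of these moves was not tested. With 14625831 to 15675012 counts per library and 3 libraries per line, 1.5-fold changes were mostly missed in simulated data, so a gene not called can still differ by that much.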

Other observations

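The gene groups and tests of explanations in this part were chosen after the results were seen, except the counts of other splits of the libraries. Genes annotated as MADS-box factors of the floral organ and floral meristem classes were mostly higher in A12: of 26 tested, 16 rose and 1 fell, with a median log2 fold change of 5.13 (also with genes at 0 set to their bound; 4.32 to 6.79 over other scalings, the block and omission of each library). The number that rose was 8 without B46 replicate 1, 6 without B46 replicate 2, 8 without B46 replicate 3 and 8 without A12 replicate 3. Camera gave an adjusted p of 4.8e-08, or adjusted p = 0.396 with an estimated correlation. The rise is not one of MADS genes at large. Matched by the DNA-binding or K-box domain instead, 44 were tested, 14 rose and 5 fell, with a median of 0.23. For these, camera gave an adjusted p of 0.012 (adjusted p = 0.430 with an estimated correlation). MADS16 (Zm00004b029254), a petal and stamen identity factor, rose from 0.558 ± 0.253 to 45.1 ± 25.7 CPM, and MADS5 (Zm00004b031849) from 8.22 ± 4.05 to 93.2 ± 9.13 CPM (SD, n = 3; edgeR adjusted p = 0.0018 and 0.0032). The member that fell is annotated as MADS20 (Zm00004b038157; log2 fold change -3.58, SE 0.46, edgeR adjusted p = 0.0059). The median of the group relative to the B46 mean was 5.09, 2.47 and 4.004 in A12 replicates 1, 2 and 3. Photosynthesis genes ordered these 3 libraries alike, at 1.18, -0.63 and 0.26. The 4 tested MADS genes of the SVP class, which in rice act in the inflorescence before floral organs form, all fell: MADS55-like Zm00004b022967 from 121 ± 46.9 to 2.43 ± 0.3 CPM, Zm00004b015192 from 65.1 ± 24.0 to 1.47 ± 0.958, Zm00004b031581 from 44.7 ± 4.98 to 12.5 ± 4.75, and MADS47-like Zm00004b000584 from 104 ± 81.5 to 2.95 ± 0.811. Between 3 and 4 of them were called across those alternatives, Zm00004b031581 being lost without B46 replicate 2 (0.0531) or A12 replicate 3 (edgeR adjusted p = 0.0584). None of the floral or SVP-class genes lies in the 145 to 185 Mb block.

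Members of other regulator families were called as well. Of 14 genes with the ALOG domain, found in regulators of organ boundaries and panicle form, 9 fell and 1 rose (median -2.55, range -3.36 to -2.004 over those alternatives), though 3 fell without A12 replicate 3. G1-like4 genes Zm00004b014415 and Zm00004b006963 had log2 fold changes of -5.94 (SE 0.49) and -6.84 (SE 0.85), while that of G1 (Zm00004b034768), a sterile lemma factor in rice, was 3.68 (SE 0.49; edgeR adjusted p = 0.0013, 0.0052 and 0.0065). B46 replicate 3 stood apart in these genes: the ALOG median relative to the B46 mean was -0.67, -0.24 and 0.88 in B46 replicates 1, 2 and 3, and Zm00004b006963 had 526, 889 and 2942 reads there. Both G1-like4 calls held without that library. Of 10 genes with the SRS domain of the SHORT INTERNODES class, linked to auxin synthesis and carpel development, 8 rose (median 1.25, range 1.06 to 1.44), with 4 without B46 replicate 1, 5 without B46 replicate 2, 5 without A12 replicate 2 and 4 without A12 replicate 3. Zm00004b023849 rose from 6.09 ± 0.533 to 30.7 ± 2.64 CPM (edgeR adjusted p = 0.00027). Among 541 Pfam domains, called genes were enriched by Fisher's exact test in 13 and depleted in 1, and the enriched ones include these domains and MADS (19 of 38, odds ratio 9.21, Benjamini-Hochberg adjusted p = 2.1e-07). The MADS, ALOG and SRS domains passed under each of those alternatives. By camera 21 domains passed, and 0 with an estimated correlation, where 10 had an unadjusted p under 0.05. Pentatricopeptide repeat genes were rarely called, 9 of 390 (2.31%, odds ratio 0.213, adjusted p = 1.5e-06), which was lost without B46 replicate 2 (adjusted p = 0.342) or A12 replicate 3 (0.798). Of 51 homeodomain-leucine zipper genes 11 rose and 5 fell, HOX21 (Zm00004b000498) from 1.44 ± 0.266 to 30.2 ± 5.10 CPM, and of 32 TCP genes 5 rose (camera adjusted p = 0.042 and 0.012, or 0.395 and 0.430 with an estimated correlation). The numbers of homeodomain-leucine zipper genes that rose and fell were 7 and 1 without B46 replicate 1, 6 and 0 without B46 replicate 2, 14 and 9 without A12 replicate 1, 17 and 5 without A12 replicate 2, and 7 and 0 without A12 replicate 3, and 3 TCP genes rose without B46 replicate 1, B46 replicate 2 or A12 replicate 3. Of 11 YABBY genes 3 rose (camera adjusted p = 0.012, or adjusted p = 0.430 with an estimated correlation), but 0 without B46 replicate 1, B46 replicate 2 or A12 replicate 3, and 7 without B46 replicate 3. Of 11 KNOX-domain genes 2 rose (camera adjusted p = 0.720; 1 without A12 replicate 3), KNOX12 (Zm00004b005271) by 1.73 (SE 0.19, edgeR adjusted p = 0.0037).

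In the 145 to 185 Mb block, calls were mostly lower in A12. Genes absent from the teosinte segment or below detection cannot be the whole cause, since only 29.5% (95% exact interval 21.6 to 38.4) of the 122 lower calls had 3 reads or fewer in A12, and the other 86 had a median of -1.38. Poorer alignment of teosinte reads to the reference might lower genes across the block. Of its 402 tested genes, called or not, 66.7% (95% exact interval 61.8 to 71.3) had a log2 fold change below 0. On the other chromosomes 48.9% were below 0. The share in the block includes its 122 lower calls, and the block was chosen for its density of calls. It is therefore no separate sign of an effect across the block. Regulatory differences between the teosinte and maize alleles could lower genes of the block as well, but need not all go one way. No alignment rates per line are given, so the share of each explanation cannot be told.

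In the 0 to 5 Mb block, calls were mostly higher in A12. Poorer alignment of B46 reads there might raise genes across the block. Of its 194 tested genes, 62.9% (95% exact interval 55.7 to 69.7) had a log2 fold change above 0. The share below 0 was 37.1%, against 48.9% on the other chromosomes. These shares include the calls, 31 of them higher, for whose density the block was chosen. They are therefore no separate sign of an effect across the block. Regulatory differences could do the same, but need not all go one way. Without alignment rates the share of each explanation cannot be told. The sources used here do not say whether the lines differ at this end of the chromosome.

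Called floral MADS and SRS genes were mostly higher in A12 and called SVP-class and ALOG genes mostly lower, with MADS20 and G1 as exceptions. Green leaf or husk tissue among the A12 ears would dilute the genes of the ear meristem alike. The values argue against it as the cause of the falls. The 13 SVP-class and ALOG genes that fell had a median log2 fold change of -5.16. They were picked because they fell, and all 14 ALOG genes, called or not, had a median of -2.55. The point rests on the 5 genes of the KNOX and BELL list, fixed in advance, which did not fall with them. These had a median of 0.15 and a lowest value of -0.24 (KNOTTED 1, SE 0.23). For the rises, green tissue as a source stays open. Photosynthesis genes lay above the B46 mean in A12 replicates 1 and 3 (medians 1.18 and 0.26) but below it in A12 replicate 2 (-0.63), where the floral MADS genes still had a median of 2.47, and 58 of 79 photosynthesis genes had a log2 fold change above 0. That list passed camera without A12 replicate 2 (adjusted p = 1.3e-05). A hypothesis is that A12 ears were collected at a slightly later developmental stage, which could change all 4 groups together. Differences between libraries of a line would follow the difference between lines only if stage also varied between those libraries. The highest absolute correlation across genes was 0.399 in A12 but 0.122 in B46. It cannot decide the question, since pools of at least 50 plants can even out stage within a line. In the groups themselves B46 replicate 3 did lie on the side away from A12, with medians relative to the B46 mean of 0.58 for SVP-class, 0.88 for ALOG and -0.38 for floral MADS genes, against -0.38, -0.67 and 0.05 in replicate 1 and -0.20, -0.24 and 0.36 in replicate 2. The labels give both lines the same stage window and no finer measure, so stage and genotype cannot be told apart here, and an effect of the segment on floral timing stays open.

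The 6 libraries can be split 3 against 3 in 10 ways, which is too few for a share under 0.05. The real split gave 2242 called genes, 337 on chromosome 5, 8 windows, a difference of 75 between lower and higher calls in them, 3 families and 1975 genes from FPKM. The highest of the other splits gave 0 for each with the same tools, so 1 of 10 splits was as large for each. In edgeR the other splits had 27 to 2051 genes at an unadjusted p under 0.05. The values for chromosome 5, windows, direction and families come from the edgeR calls, so their 0 follows from 0 calls and is no separate check. The other splits also mix the lines within a group, which widens the spread there. For gene lists, 7 of the 10 splits passed at least the real number of 3, and the highest passed 9, so camera with the preset correlation also passes lists between arbitrary sets of these libraries.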
